A study of Mus musculus with 16 samples.

How the data were processed

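RNA was measured on 16 Affymetrix Mouse Gene 2.1 ST arrays, 1 per sample, in 6 groups. The cells came from a mouse embryonic stem cell line in which doxycycline (Dox) switches on the transcription factors Gfi1, Pou4f3 and Atoh1 and a Myo7a promoter drives the fluorescent protein mVenus. Stem cells were grown as floating embryoid bodies (EBs). Treatment with Dox, or with Dox and retinoic acid (RA), began on day 4, and cells with mVenus signal, called induced hair cell-like cells (iHCs), were sorted by flow cytometry after 4 or 8 days of treatment, on day 8 or day 12. The control EBs of the same days were neither treated nor sorted, so the effect of the treatment and that of the sort cannot be separated. The 4 iHC groups (Dox day 8, Dox day 12, Dox+RA day 8, Dox+RA day 12) had 3 replicates each and the control EBs had 2 at each day. The submitters call them biological replicates from separate RNA preparations. The strip, scan date and any other batch of an array are not given in the sources used here.

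The deposited values are log2 RMA values, made by the authors with Affymetrix Expression Console per the submitters' processing notes, which give no version; RMA corrects for background, sets the arrays to a common distribution and summarises the probes of a transcript cluster. The values were checked against this unit: they ran from 1.44 to 12.3 over all arrays, the array means from 5.03 to 5.09 and the array medians from 4.67 to 4.82, with 0 missing values. They were used as deposited. RMA compresses changes at low signal, the table has no detection calls, and the probes of Gfi1, Pou4f3, Atoh1 and Myo7a may read transgene and endogenous transcripts alike. The number of arrays limits the precision.

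Of the 33708 entries in the table, 23521 carry 1 gene symbol, 1814 carry several and 8373 carry none. Of those with 1 symbol, 23328 were matched by Entrez gene ID to the RefSeq gene table and 0 symbols needed updating. For 1082 genes with more than 1 entry, the entry with the highest mean over the 16 arrays was used, which left 22180 genes to test. Entries with no symbol or several were left out of the comparisons.

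All 22180 genes were fitted in limma 3.58.1 (R 4.3.3) with a mean for each of the 6 groups, lmFit, contrasts.fit and eBayes at their defaults. There were 12 contrasts: 9 differences between 2 groups and 3 interactions. A gene was called when limma's moderated test gave a Benjamini-Hochberg adjusted p under 0.05 over all genes of that contrast, and the number with a change of 2-fold or more is given beside the count. Every p printed for a gene is this adjusted p, and ± beside a log2 difference is limma's standard error. Levels are group means with SD and n. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

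The 21 gene lists were factors of the inducible line, hair cell identity, stereocilia and mechanotransduction, synapse and exocytosis, Notch signalling, otic and supporting cell, neuronal, neural progenitor, retinoic acid response, Hox paralogues 1 to 5, Hox paralogues 6 to 13, pluripotency, mesoderm and cardiac, endoderm, blood and endothelium, mesenchyme and neural crest, surface epithelium, Merkel cell, cell cycle, cyclin-dependent kinase inhibitors, and immediate early and dissociation stress. Each was tested as a whole with camera of limma at its preset correlation of 0.01, with p adjusted over the 21 lists of a comparison, and again with the correlation estimated from the data. Members without an entry of their own on the table were not analysed here. Members were also counted with p adjusted over the list alone. The lists, the contrasts, the tests, the choice of named genes and 11 kinds of alternative processing were fixed before the data were examined.

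The named genes of each comparison are Gfi1, Pou4f3, Atoh1 and Myo7a, then the 10 largest rises and the 10 largest falls by log2 difference among called genes whose arrays did not overlap between the groups (5 and 5 for an interaction, without the condition on overlap, and for the control EBs over time), and up to 4 called members of each list with the largest difference, or 2 members as values where none was called. Predicted genes, microRNAs, small nucleolar RNAs and unnamed cDNAs were passed over. The text gives a part of these genes, chiefly those that kept their call under every alternative.

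Replicate numbers were checked for pairing with the correlation between arrays of 2 groups after each gene's group mean was taken out. In each of the 6 pairs of iHC groups all 3 same-numbered pairs had r above 0.1 (range 0.147 to 0.513), so iHC arrays of equal number varied together. The labels do not say that equal numbers share a batch, and the main fit has no replicate term. Counts with the replicate number as a block (a fixed term for each number in the fit) stand beside the iHC comparisons. Control EBs have only 2 pairs with any group, too few for such a statement.

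The alternatives set beforehand were a fit on the compared arrays alone, a variance trend with robust estimation, array weights, the replicate block, quantile scaling applied again, cyclic loess, equal array medians, leaving out genes below the 40th percentile of signal (15812 genes remained), the mean of a gene's entries, all entries of the table, and leaving out each array in turn. For the lists they were the estimated correlation, the block, the filter on signal and the variance trend. Leaving out the Dox iHCs with replicate number 3 of both days, 7 further gene lists, the lists under the 3 scalings and with each array left out, and the day 12 choice of genes for the implied share of EB RNA and for the stereocilia test were added after seeing the data. The 7 further lists are interferon-stimulated genes, imprinted genes, ribosomal protein genes, ion channel subunits, collagens, protocadherins and the microRNA genes between Dlk1 and Dio3, and their p values are adjusted over these 7.

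The method was tested on simulated data with 22180 genes, the group sizes of the study and 200 changed genes. For Dox iHCs against control EBs at day 8, 50%, 88%, 96% and 100% of genes changed by 0.5, 1, 2 and 3 on the log2 scale were called, with 12 of 179 calls false. For Dox+RA against Dox at day 8 the shares were 44%, 92%, 100% and 100% (10 of 178 false), for Dox iHCs over time 42%, 96%, 100% and 100% (8 of 177), for control EBs over time 28%, 92%, 96% and 98% (4 of 161), and for the interaction of RA and day 10%, 80%, 96% and 100% (9 of 152). With no change simulated, 0 genes were called in all 12 contrasts, and camera called 1 list in 3 of them. The simulated noise was independent between genes and between arrays. These rates therefore need not hold for the data, where genes of a list and arrays of equal number vary together.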

Results

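The series asks how mouse cells change when the transcription factors Gfi1, Pou4f3 and Atoh1 are switched on together by Dox in EBs, and what RA adds to the switch. Sorted Myo7a:mVenus-positive iHCs treated with Dox or with Dox and RA were compared with untreated, unsorted control EBs at day 8 and at day 12, with each other, and over time. Signal of 22180 genes was available on 16 arrays, 3 in each iHC group and 2 in each control EB group. Each difference from control EBs includes both treatment and sort.

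Replicate arrays of a group resembled one another closely, with correlations from 0.984 to 0.995. Arrays of different iHC groups correlated at 0.967 to 0.992, those of the control EBs at the 2 days at 0.981 to 0.990, and iHCs with control EBs at 0.894 to 0.948. The first principal component held 74.8% of the variance and the second 7.68%. Control EBs lay between -94.6 and -90.0 on the first component, and all iHCs lay far from them. Among the Dox iHCs of day 8 the positions were 21.9, 8.4 and -0.586 for replicates 1, 2 and 3, and at day 12 they were 45.0, 36.9 and 22.5. The Dox+RA iHCs stood at 36.7, 33.6 and 32.5 at day 8 and at 45.6, 47.1 and 41.3 at day 12.

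**Figure D1:**
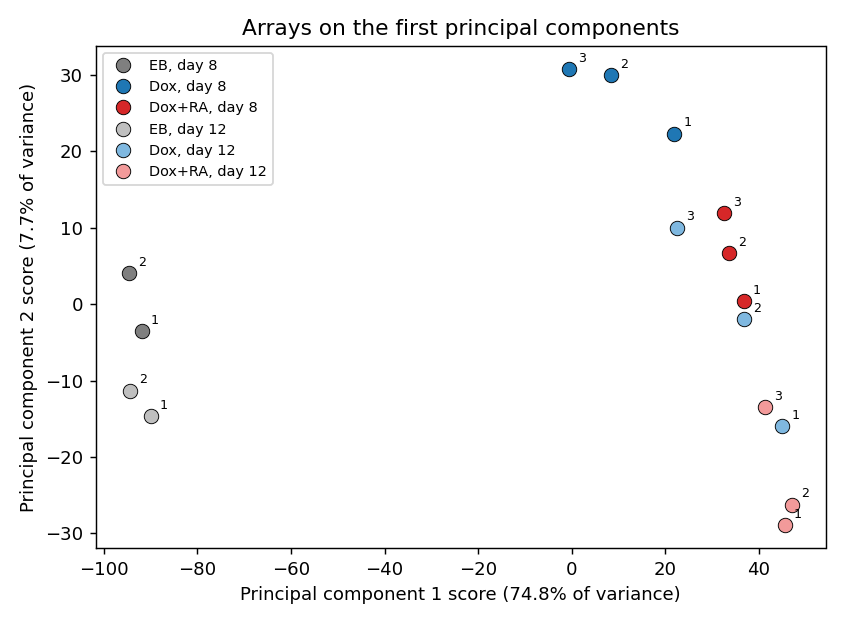
Position of each of the 16 arrays on the first (horizontal, 74.8% of variance) and second (vertical, 7.68%) principal component of the log2 RMA values, with 1 point per array, colour for the group and the replicate number beside each point. Control EBs lie between -94.6 and -90.0 on the first component, apart from all iHCs.

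The first comparison asks what sets Dox iHCs apart from control EBs at day 8. The 3 induced factors were far higher in the iHCs. Atoh1, a basic helix-loop-helix factor needed to form hair cells, stood at 10.93 ± 0.05 (SD, n = 3) against 4.89 ± 0.25 (n = 2). Pou4f3, a POU factor needed for hair cell survival, stood at 11.31 ± 0.08 against 5.47 ± 0.49, and the zinc-finger repressor Gfi1 at 11.05 ± 0.07 against 6.59 ± 0.18. Myo7a, the unconventional myosin whose promoter drives the reporter, rose by 1.98 ± 0.28 (adjusted p = 4.2e-05). Hair cell identity genes rose in 16 of 25 cases (camera adjusted p = 7.2e-10), and mesenchyme genes fell in 20 of 25 (adjusted p = 1.4e-12). In limma 7675 genes were called, 34.6% of those tested, with 3490 higher and 4185 lower in iHCs, and 2640 of them differed 2-fold or more.

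The largest rises at day 8 were Ccer2 (log2 difference 6.23 ± 0.15, adjusted p = 1.1e-12), Atoh1 (6.03 ± 0.14), Pou4f3 (5.84 ± 0.19), the neuronal helix-loop-helix gene Nhlh1 (5.71 ± 0.21), and Ecel1 (5.70 ± 0.16). They were followed by somatostatin (Sst, 5.70 ± 0.64), the receptor phosphatase Ptprz1 (5.51 ± 0.39), the axonal adhesion gene Cntn2 (5.30 ± 0.15), the noncoding RNA Miat (5.22 ± 0.19) and gamma-synuclein (Sncg, 5.20 ± 0.14). The largest falls were the matrix genes Postn (-6.11 ± 0.39, adjusted p = 1.6e-08), Lum (-5.40 ± 0.14) and Dcn (-4.64 ± 0.28), the chemokine Ccl3 (-4.88 ± 0.27) and Capn6 (-4.54 ± 0.42). Next came the cardiac factor Tbx20 (-4.35 ± 0.25), the protocadherin Pcdh18 (-4.34 ± 0.25), Asb4 (-4.31 ± 0.29), the uroplakin Upk1b (-4.27 ± 0.18) and Mtap (-4.17 ± 0.37).

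All 3 factors of the inducible line rose, also adjusted over the list alone (camera adjusted p = 2.1e-07). Of 25 hair cell identity genes 16 rose, 0 fell and 9 were not called (adjusted p = 7.2e-10), with the same 16 adjusted over the list alone. Among them were the homeobox genes Barhl1 (4.47 ± 0.24) and Lhx3 (4.08 ± 0.20) and the Notch ligand Jag2 (3.42 ± 0.17). Stereocilia and mechanotransduction genes rose in 16 of 32 cases, fell in 0 and were not called in 16 (adjusted p = 2.0e-06, adjusted p = 0.091 with an estimated correlation), again 16 adjusted over the list alone. They included the tip-link cadherins Cdh23 (3.98 ± 0.19) and Pcdh15 (3.61 ± 0.13), the transduction channel partner Tmie (3.66 ± 0.17) and Myo15, a myosin needed for stereocilia to lengthen (3.56 ± 0.29). Of 21 synapse and exocytosis genes 15 rose, 2 fell and 4 were not called (adjusted p = 1.9e-07; 15 and 2 adjusted over the list alone). They included the synaptic vesicle genes Syt1 (4.00 ± 0.18) and Syp (3.19 ± 0.20), the SNARE gene Snap25 (3.17 ± 0.22) and the calcium-binding Cabp2 (3.10 ± 0.19). The neuronal list had 20 rises, 2 falls and 13 members not called (adjusted p = 3.0e-10; 21 and 2 adjusted over the list alone). The neurofilament gene Nefl changed by 5.19 ± 0.34, Ebf1 by 3.93 ± 0.14 and Pou4f1 by 3.64 ± 0.12. The 12 Merkel cell genes, a list of another mechanosensory cell that also needs Atoh1, had 7 rises, 0 falls and 5 not called (adjusted p = 4.1e-05; 8 and 0 adjusted over the list alone). Rab3c (4.68 ± 0.33) and the mechanically gated channel Piezo2 (3.01 ± 0.25) were among the rises. Except for stereocilia, these lists kept their call with an estimated correlation.

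Notch signalling genes rose in 11 cases of 20, fell in 4 and were not called in 5 (adjusted p = 0.0045, adjusted p = 0.24 with an estimated correlation; 11 and 5 adjusted over the list alone). The ligand genes Dll3 (4.85 ± 0.24) and Dll4 (1.79 ± 0.17) and the fringe genes Mfng (4.16 ± 0.10) and Lfng (2.77 ± 0.23) were among the rises. The otic and supporting cell list moved both ways, with 6 rises, 6 falls and 15 not called (adjusted p = 0.47; 6 and 6 adjusted over the list alone), and Eya1 (2.5 ± 0.19), Fbxo2 (2.34 ± 0.24) and Prox1 (2.28 ± 0.25) rose. Neural progenitor genes had 6 rises, 4 falls and 14 not called (adjusted p = 0.59, with the same counts adjusted over the list alone), and the glutamate transporter Slc1a3 fell by 4.03 ± 0.15. Retinoic acid response genes had 4 rises, 7 falls and 11 not called (adjusted p = 0.76; the same adjusted over the list alone), with a median of 0.10, a mean of -0.15 and a test that points down. Stra6, the receptor for retinol-binding protein, rose by 3.06 ± 0.23 and Meis1 fell by 3.32 ± 0.28.

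The Hox genes of paralogues 6 to 13 fell in 13 cases of 23, rose in 0 and were not called in 10 (adjusted p = 6.9e-08; 0 and 14 adjusted over the list alone). Hoxc8 changed by -2.5 ± 0.16 and Hoxc6 by -2.33 ± 0.15. Paralogues 1 to 5 had 1 rise, 5 falls and 7 not called (adjusted p = 0.12; the same adjusted over the list alone). Hoxc4 changed by -1.09 ± 0.16. Pluripotency genes fell in 18 of 24 cases, rose in 0 and were not called in 6 (adjusted p = 2.9e-08, adjusted p = 0.091 with an estimated correlation; 0 and 19 adjusted over the list alone). Among them were Utf1 (-3.0 ± 0.27) and Nanog (-2.89 ± 0.33). Mesoderm and cardiac genes had 2 rises, 13 falls and 10 not called (adjusted p = 1.7e-05, adjusted p = 0.065 with an estimated correlation; 2 and 15 adjusted over the list alone). The atrial myosin light chain gene Myl7 changed by -4.01 ± 0.43 and the cardiac factors Hand1 by -3.53 ± 0.19 and Hand2 by -3.38 ± 0.13. Endoderm genes had 1 rise, 11 falls and 14 not called (adjusted p = 0.00025, adjusted p = 0.34 with an estimated correlation; 1 and 13 adjusted over the list alone). Dab2 changed by -2.75 ± 0.31 and Gata6 by -2.60 ± 0.39. Blood and endothelium genes fell in 22 of 24 cases, with 1 rise and 1 not called (adjusted p = 2.9e-11; 1 and 22 adjusted over the list alone). They included the embryonic globins Hbb-bh1 (-3.74 ± 0.18) and Hbb-y (-3.21 ± 0.20) and the endothelial Emcn (-3.32 ± 0.25) and Tek (-2.83 ± 0.36). Mesenchyme and neural crest genes fell in 20 of 25 cases, with 1 rise and 4 not called (adjusted p = 1.4e-12; 2 and 20 adjusted over the list alone), and the collagen gene Col3a1 changed by -4.00 ± 0.16.

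Cell cycle genes fell in 27 of 29 cases, with 0 rises and 2 not called (adjusted p = 4.3e-15, adjusted p = 0.11 with an estimated correlation; 0 and 28 adjusted over the list alone). The spindle checkpoint genes Bub1 (-2.49 ± 0.21) and Bub1b (-2.27 ± 0.20), the helicase subunit Mcm3 (-2.28 ± 0.24) and the ribonucleotide reductase subunit Rrm2 (-2.25 ± 0.24) led them. Of 7 cyclin-dependent kinase inhibitors 3 rose and 4 were not called (adjusted p = 0.12; 3 and 1 adjusted over the list alone). Cdkn1c changed by 1.75 ± 0.26 and Cdkn2d by 1.23 ± 0.17. Immediate early and dissociation stress genes had 5 rises, 4 falls and 16 not called (adjusted p = 0.53; the same adjusted over the list alone). Gadd45b changed by 2.42 ± 0.18, Btg2 by 1.53 ± 0.17 and Klf6 by -1.63 ± 0.26. The surface epithelium list had 3 rises, 6 falls and 10 not called (adjusted p = 0.13; 3 and 7 adjusted over the list alone). The claudin gene Cldn3 changed by 3.15 ± 0.25 and Grhl3 by -1.89 ± 0.16. Without Dox day 8 replicate 3 its adjusted p was 0.0413, and with the replicate block it was 0.0281, the low end of a range to 0.643 over all alternatives.

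**Figure D2:**
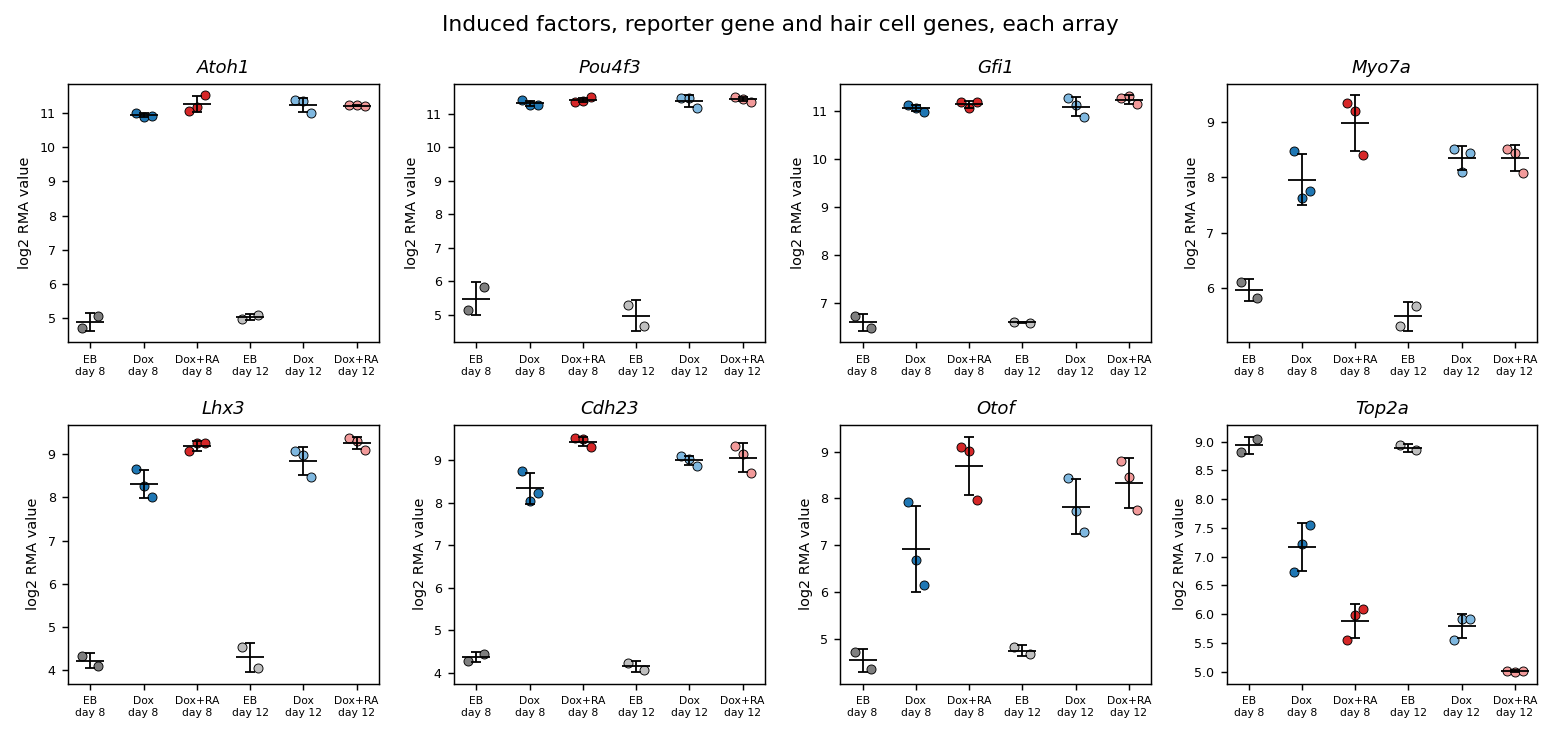
Log2 RMA value (vertical) of Atoh1, Pou4f3, Gfi1, Myo7a, Lhx3, Cdh23, Otof and Top2a in the 6 groups (horizontal), with 1 point per array, a line at the group mean and bars for the SD (n = 2 for control EBs, n = 3 for iHCs). Atoh1 stands at 10.93 in Dox iHCs and 4.89 in control EBs of day 8.

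The same question at day 12 gave 9055 called genes, 40.8% of those tested, of which 4252 were higher and 4803 lower in Dox iHCs and 3420 differed 2-fold or more. Pou4f3 stood at 11.38 ± 0.17 (SD, n = 3) against 4.98 ± 0.45 (n = 2), and Myo7a rose by 2.84 ± 0.28 (adjusted p = 7.6e-07). The largest rises were Ptprz1 (7.0 ± 0.39), Pou4f3 (6.40 ± 0.19), Ccer2 (6.25 ± 0.15), Atoh1 (6.20 ± 0.14), Nhlh1 (6.11 ± 0.21), and Rab3c (5.89 ± 0.33). The potassium channel gene Kcnk9 (5.53 ± 0.42), the phospholipase gene Plch2 (5.40 ± 0.28), Pcdh9 (5.27 ± 0.24) and Cntn2 (5.25 ± 0.15) followed. Lum (-5.84 ± 0.14), Postn (-5.82 ± 0.39), Dcn (-5.74 ± 0.28), Pcdh18 (-5.01 ± 0.25) and the growth factor receptor gene Pdgfra (-4.93 ± 0.28) fell most. The matrix gene Frem1 (-4.91 ± 0.22), Capn6 (-4.77 ± 0.42), Col1a2 (-4.74 ± 0.17), Mab21l2 (-4.71 ± 0.40) and Colec12 (-4.67 ± 0.28) fell next.

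At day 12 all 3 factors rose (camera adjusted p = 2.4e-06). Hair cell identity genes had 17 rises, 0 falls and 8 not called (adjusted p = 2.2e-09), with the RNA-binding Rbm24 at 4.99 ± 0.27. Stereocilia genes had 24 rises, 1 fall and 7 not called (adjusted p = 2.2e-09). Cdh23 changed by 4.85 ± 0.19, Myo15 by 4.61 ± 0.29 and the transduction complex gene Lhfpl5 by 3.98 ± 0.33. Synapse genes had 16 rises, 2 falls and 3 not called (adjusted p = 2.4e-08; 17 and 2 adjusted over the list alone). The presynaptic scaffold gene Pclo changed by 4.12 ± 0.17 and the vesicular monoamine transporter gene Slc18a2 by 4.10 ± 0.12. Merkel cell genes had 6 rises, 1 fall and 5 not called (adjusted p = 0.00069). Hox paralogues 6 to 13 had 0, 14 and 9 (adjusted p = 4.9e-07), with Hoxa13 at -2.71 ± 0.14. Mesenchyme genes had 0, 21 and 4 (adjusted p = 1.7e-15; 22 falls adjusted over the list alone). These lists were called with an estimated correlation as well. The neuronal list had 18 rises, 5 falls and 12 not called (adjusted p = 7.0e-05, adjusted p = 0.18 with an estimated correlation). Pluripotency genes fell in 17 of 24 cases (adjusted p = 8.9e-06, adjusted p = 0.18 with an estimated correlation). Endoderm genes fell in 16 of 26 (adjusted p = 3.9e-07, adjusted p = 0.18 with an estimated correlation), with the albumin gene Alb at -4.04 ± 0.16. Blood and endothelium genes fell in 17 of 24 (adjusted p = 6.9e-07, adjusted p = 0.11 with an estimated correlation). Mesoderm and cardiac genes had 3 rises and 12 falls (adjusted p = 0.0030, adjusted p = 0.18 with an estimated correlation). Cell cycle genes had 28 falls of 29 (adjusted p = 1.9e-16, adjusted p = 0.12 with an estimated correlation). Cdk1 changed by -3.30 ± 0.24 and Mki67 by -3.15 ± 0.25. Hox paralogues 1 to 5 had 1 rise, 8 falls and 4 not called (adjusted p = 0.016, adjusted p = 0.26 with an estimated correlation). The call was also lost with dim genes left out (adjusted p = 0.0743) or without control EB day 12 replicate 1 (adjusted p = 0.084; range over alternatives 0.00443 to 0.265).

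Dox+RA iHCs were set against control EBs to ask what the cells look like when RA is present too. At day 8 the factor genes were again far higher, with Atoh1 at 11.25 ± 0.23 (SD, n = 3) against 4.89 ± 0.25 (n = 2), and Myo7a rose by 3.0 ± 0.28 (adjusted p = 4.3e-07). In limma 9223 genes were called (41.6%), 4347 higher and 4876 lower, and 3504 differed 2-fold or more. Ptprz1 (6.54 ± 0.39), Ccer2 (6.53 ± 0.15), Atoh1 (6.35 ± 0.14), Nhlh1 (6.28 ± 0.21), Pou4f3 (5.94 ± 0.19), Miat (5.79 ± 0.19), Tmem255b (5.71 ± 0.34), Cntn2 (5.55 ± 0.15) and Rab3c (5.53 ± 0.33) rose most. The deepest falls were Postn (-7.26 ± 0.39), Lum (-5.38 ± 0.14), Capn6 (-5.16 ± 0.42), Myl7 (-5.09 ± 0.43), Ccl3 (-4.92 ± 0.27), Tbx20 (-4.87 ± 0.25), the hyaluronan synthase gene Has2 (-4.82 ± 0.32) and Pcdh18 (-4.81 ± 0.25). Hair cell identity genes had 17 rises, 0 falls and 8 not called (adjusted p = 4.7e-10; 21 rises adjusted over the list alone). Stereocilia genes had 22, 1 and 9 (adjusted p = 3.5e-09), with Cdh23 at 5.08 ± 0.19. Synapse genes had 15, 2 and 4 (adjusted p = 2.4e-07; 16 and 2 adjusted over the list alone), with the otoferlin gene Otof, needed for release at hair cell synapses, at 4.14 ± 0.47. Neuronal genes had 21, 1 and 13 (adjusted p = 1.2e-08). Cell cycle genes fell in 28 of 29 cases (adjusted p = 3.7e-17, adjusted p = 0.094 with an estimated correlation). Hox paralogues 1 to 5 had 5 rises, 4 falls and 4 not called (adjusted p = 0.46), with a median of -0.05, a mean of 0.51 and a test that points up, and Hoxb5 changed by 3.53 ± 0.20 and Hoxb1 by 1.94 ± 0.38. Retinoic acid response genes had 7 rises, 5 falls and 10 not called (adjusted p = 0.41).

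At day 12 Dox+RA iHCs differed from control EBs in 9927 genes (44.8%), 4964 higher and 4963 lower, with 3783 differing 2-fold or more. Ptprz1 (7.29 ± 0.39), Pou4f3 (6.45 ± 0.19), Ccer2 (6.42 ± 0.15), Nhlh1 (6.33 ± 0.21), Plch2 (5.93 ± 0.28), Kcnk9 (5.92 ± 0.42) and the LIM homeobox gene Lhx1 (5.39 ± 0.33) were among the largest rises. Postn (-6.10 ± 0.39), Lum (-5.81 ± 0.14), Dcn (-5.44 ± 0.28), Pdgfra (-5.16 ± 0.28) and the linker histone gene H1f5 (-4.81 ± 0.17) were among the largest falls. Stereocilia genes had 24 rises, 1 fall and 7 not called (adjusted p = 1.5e-08, adjusted p = 0.061 with an estimated correlation). Myo15 changed by 5.10 ± 0.29. Hair cell identity genes had 17, 1 and 7 (adjusted p = 1.2e-07, adjusted p = 0.061 with an estimated correlation), with the nicotinic receptor subunit Chrna10 at 5.04 ± 0.59. Mesenchyme genes had 0, 23 and 2 (adjusted p = 7.0e-16, adjusted p = 0.061 with an estimated correlation). Cell cycle genes had 0, 28 and 1 (adjusted p = 1.7e-17, adjusted p = 0.12 with an estimated correlation). Top2a changed by -3.88 ± 0.20. In this comparison each of the 13 lists called at the preset correlation was without a call when the correlation was estimated.

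Calls were largely shared between days, which have control arrays of their own. In Dox iHCs 2819 genes were higher than in control EBs at both days, where 669 would be shared if the calls were independent, and 3480 were lower at both (906 if independent). In Dox+RA iHCs the shared counts were 3411 higher (973) and 3972 lower (1091). The shared genes made up 80.8% and 83.2% of the day 8 calls for Dox and 78.5% and 81.5% for Dox+RA.

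**Figure D3:**
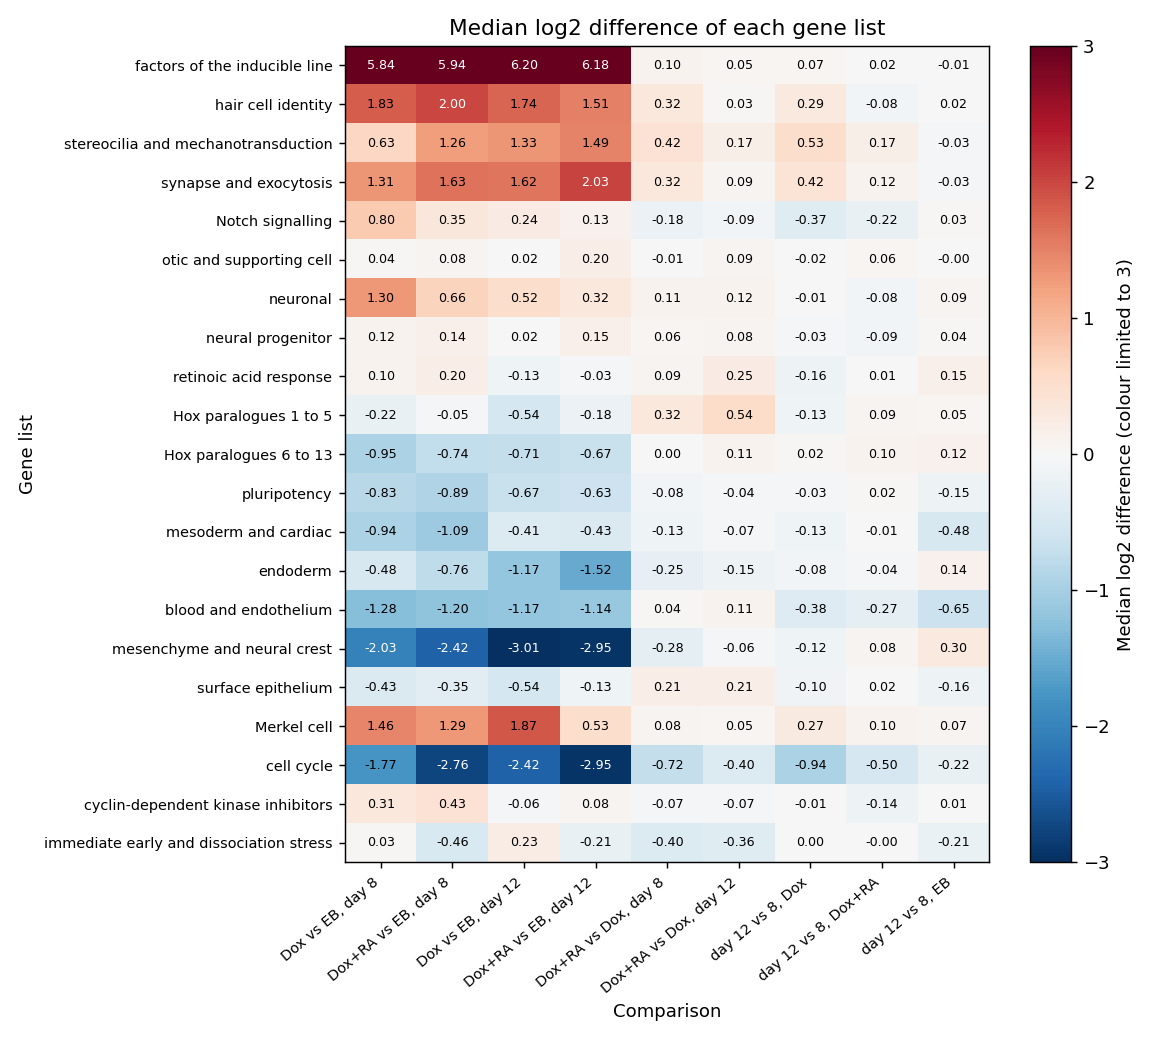
Median log2 difference of the 21 gene lists (vertical) in 9 comparisons (horizontal), with colour from negative to positive values limited to 3 on either side. The mesenchyme and neural crest list has a median of -3.01 and the stereocilia list one of 1.33 in Dox iHCs against control EBs at day 12.

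The effect of RA itself was asked by setting Dox+RA iHCs against Dox iHCs. At day 8 Hoxb5, Cyp26b1 and Oasl2 were among the genes that rose with RA, and Bgn and Top2a among those that fell. Hoxb5 stood at 8.97 ± 0.20 (SD, n = 3) against 6.12 ± 0.09 (n = 3). The factor genes had log2 differences of 0.32 ± 0.13 for Atoh1 (adjusted p = 0.18), 0.10 ± 0.17 for Pou4f3 (adjusted p = 0.83) and 0.09 ± 0.10 for Gfi1 (adjusted p = 0.74). In limma 1094 genes were called (4.93%), 454 higher and 640 lower with RA, of which 250 differed 2-fold or more. With replicate numbers as a block 2436 genes were called.

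The largest rises with RA at day 8 were Hoxb5 (2.85 ± 0.18, adjusted p = 1.9e-06), the calcium-binding Cib3 (2.47 ± 0.24) and the retinoic acid-binding Crabp1 (2.0 ± 0.38). Also among them were the interferon-induced genes Oasl2 (2.84 ± 0.25), Usp18 (2.67 ± 0.26), Oas1b (2.39 ± 0.24), Parp12 (2.21 ± 0.26), Mx2 (2.13 ± 0.12), Gbp7 (2.04 ± 0.16) and Ddx58, a sensor of foreign RNA (1.97 ± 0.21). Falls were led by the matrix and matrix-associated genes Bgn (-2.46 ± 0.29, adjusted p = 0.00030), Igfbp5 (-2.31 ± 0.31) and Vcan (-2.21 ± 0.35). The connexin gene Gja1 (-2.08 ± 0.35), the forkhead gene Foxc1 (-1.91 ± 0.23), Dapl1 (-1.87 ± 0.30) and Edil3 (-1.83 ± 0.26) fell too. Of 45 interferon-stimulated genes, a list added after seeing the data and so not independent evidence, 24 rose (camera adjusted p = 5.7e-31, adjusted p = 0.0026 with an estimated correlation).

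Stereocilia and mechanotransduction genes rose in 12 of 32 cases with 0 falls and 20 not called (adjusted p = 1.5e-12, adjusted p = 0.12 with an estimated correlation; 18 rises adjusted over the list alone). Myo3b changed by 1.5 ± 0.29. Hair cell identity genes had 3 rises, 1 fall and 21 not called (adjusted p = 8.6e-06, adjusted p = 0.15 with an estimated correlation; 5 and 1 adjusted over the list alone). The splicing regulator Srrm4 changed by 1.53 ± 0.20. Synapse genes had 3, 1 and 17 (adjusted p = 0.0027, adjusted p = 0.37 with an estimated correlation; 8 and 2 adjusted over the list alone). Cabp2 changed by 1.05 ± 0.17. Hox paralogues 1 to 5 had 4 rises, 0 falls and 9 not called (adjusted p = 3.5e-07, adjusted p = 0.12 with an estimated correlation; 6 and 1 adjusted over the list alone). Besides Hoxb5 the rises were Hoxb4 (1.76 ± 0.21), Hoxb3 (1.49 ± 0.14) and Hoxb2 (1.24 ± 0.17). Retinoic acid response genes had 4, 0 and 18 (adjusted p = 0.0016, adjusted p = 0.15 with an estimated correlation; 8 rises adjusted over the list alone). The retinoic acid-degrading enzyme gene Cyp26b1 changed by 1.63 ± 0.21 and Meis2 by 1.10 ± 0.13. Cell cycle genes fell in 13 of 29 cases, with 16 not called (adjusted p = 2.7e-17, adjusted p = 0.20 with an estimated correlation; 25 falls adjusted over the list alone). They included Top2a (-1.29 ± 0.18) and Cdk1 (-1.26 ± 0.22). Mesenchyme genes had 0, 3 and 22 (adjusted p = 0.00020, adjusted p = 0.41 with an estimated correlation; 6 falls adjusted over the list alone). Stress genes had 0, 2 and 23 (adjusted p = 0.00025, adjusted p = 0.52 with an estimated correlation). Ier3 changed by -1.20 ± 0.23. Elsewhere Notch2 (-1.28 ± 0.25), the Notch target Hey1 (-1.20 ± 0.21), the peripherin gene Prph (-1.41 ± 0.17) and Cbln2 (-0.73 ± 0.13) fell. The Notch ligand Dll1 (1.11 ± 0.14), Fbxo2 (1.16 ± 0.21), Sox21 (1.06 ± 0.18) and the keratin gene Krt20 (1.31 ± 0.23) rose.

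Without replicate 3 of the Dox iHCs at both days, the arrays of each day nearest to the control EBs on the first principal component, 687 genes were called. Notch genes (2, 5 and 13; adjusted p = 0.040, adjusted p = 0.52 with an estimated correlation; range over alternatives 0.00993 to 0.522) lost their call without Dox+RA day 8 replicate 1 (adjusted p = 0.25) or Dox day 8 replicate 2 (0.21). They also lost it with dim genes left out (0.141), quantile scaling (0.0865) or cyclic loess (0.101). For mesoderm genes (0, 0 and 25; adjusted p = 0.036, adjusted p = 0.52 with an estimated correlation; range 0.0140 to 0.516) the values were 0.097 without Dox+RA day 8 replicate 1, 0.16 without Dox day 8 replicate 3 and 0.166 with dim genes left out. For endoderm genes (0, 0 and 26; adjusted p = 0.013, adjusted p = 0.60 with an estimated correlation; range 0.00129 to 0.600) they were 0.10 and 0.35 without the same arrays and 0.0799 with dim genes left out. Myo7a was called at 1.02 ± 0.25 (adjusted p = 0.028; range 0.00374 to 0.142). Its adjusted p was 0.118 without Dox+RA day 8 replicate 1, 0.142 without Dox day 8 replicate 2, 0.113 without Dox+RA day 8 replicate 2 and 0.118 without Dox day 8 replicate 3. The number of called genes was 625 without Dox+RA day 8 replicate 1, 333 without Dox day 8 replicate 2, 546 without Dox+RA day 8 replicate 2 and 416 without Dox day 8 replicate 3.

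**Figure D4:**
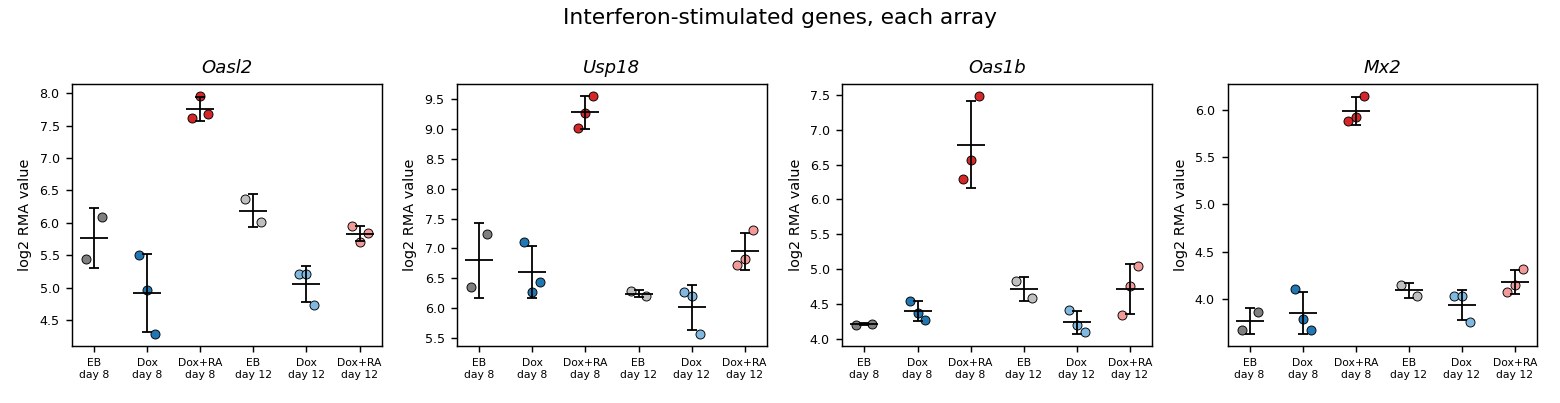
Log2 RMA value (vertical) of Oasl2, Usp18, Oas1b and Mx2 in the 6 groups (horizontal), with 1 point per array, a line at the group mean and bars for the SD (n = 2 for control EBs, n = 3 for iHCs). Usp18 stands at 9.27 in Dox+RA and 6.61 in Dox iHCs at day 8, and at 6.95 in Dox+RA iHCs at day 12.

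At day 12 the difference made by RA was smaller in count, with 205 called genes (0.92%), 85 higher and 120 lower, of which 70 differed 2-fold or more, and 2674 genes had an unadjusted p under 0.05. Cib3 (2.67 ± 0.24, adjusted p = 5.3e-05), Cyp26b1 (2.47 ± 0.21), Hoxb5 (2.31 ± 0.18) and the retinaldehyde reductase gene Dhrs3 (2.17 ± 0.24) rose most. Hoxb4 (1.76 ± 0.21), Skor2 (1.74 ± 0.18), Hoxb3 (1.56 ± 0.14), the meiotic cohesin gene Rec8 (1.48 ± 0.16) and Hoxb2 (1.29 ± 0.17) rose too. The synaptic organiser gene Cbln2 (-2.06 ± 0.13, adjusted p = 3.9e-06) and the protocadherin gene Pcdh10 (-1.88 ± 0.16) fell. Hoxb5 stood at 8.40 ± 0.35 (SD, n = 3) against 6.09 ± 0.22 (n = 3). Atoh1 (-0.02 ± 0.13, adjusted p = 0.97), Pou4f3 (0.05 ± 0.17, adjusted p = 0.94), Gfi1 (0.15 ± 0.10, adjusted p = 0.62) and Myo7a (0.00 ± 0.25, adjusted p = 1) were close between the groups.

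Hox paralogues 1 to 5 had 5 rises, 0 falls and 8 not called (adjusted p = 1.0e-14; 10 rises adjusted over the list alone). Retinoic acid response genes had 3, 0 and 19 (adjusted p = 1.9e-06; 8 rises adjusted over the list alone). Both kept their call with an estimated correlation. Cell cycle genes as a list were lower with 0 single members called (adjusted p = 6.1e-10, adjusted p = 0.68 with an estimated correlation; 1 and 9 adjusted over the list alone). Endoderm genes (0, 0 and 26; adjusted p = 0.015, adjusted p = 0.78 with an estimated correlation; range 0.000477 to 0.780) lost their call without Dox day 12 replicate 3 (adjusted p = 0.73). Stress genes (0, 0 and 25; adjusted p = 7.0e-05, adjusted p = 0.78 with an estimated correlation; range 7.0e-08 to 0.780) lost theirs without the same array (0.41). Stereocilia genes had 1 rise and 31 not called (adjusted p = 0.058; range 0.00181 to 0.780), and the list was called without Dox day 12 replicate 1 (adjusted p = 0.0018) or Dox+RA day 12 replicate 3 (0.0025). The count was 393 without Dox day 12 replicate 1, 80 without Dox+RA day 12 replicate 1, 55 without replicate 2 of either Dox or Dox+RA at day 12 and 360 without Dox+RA day 12 replicate 3. With replicates as a block it was 722, and with the 6 compared arrays alone 29.

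**Figure D5:**
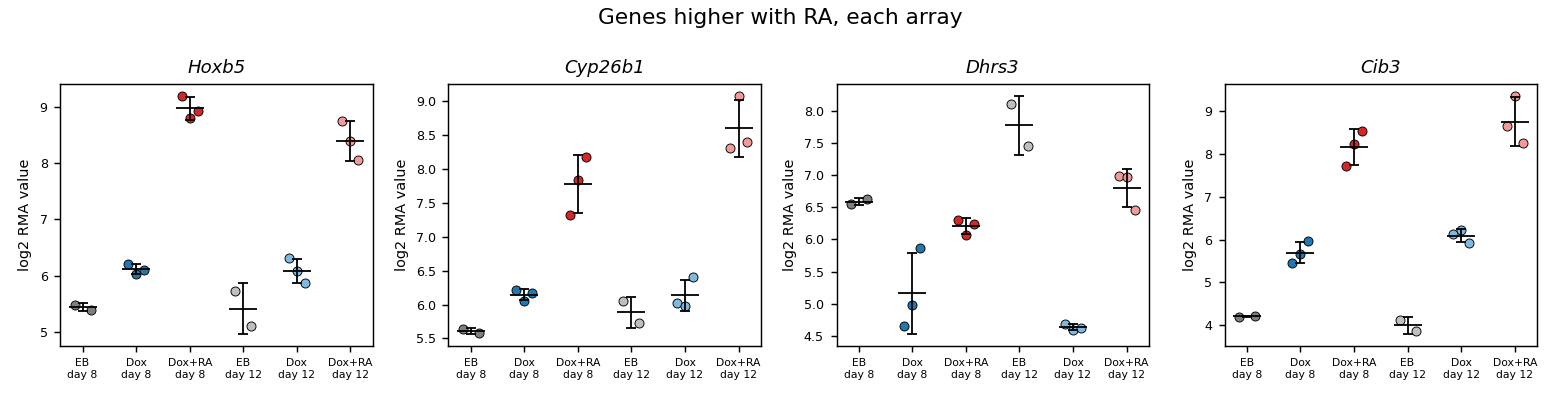
Log2 RMA value (vertical) of Hoxb5, Cyp26b1, Dhrs3 and Cib3 in the 6 groups (horizontal), with 1 point per array, a line at the group mean and bars for the SD (n = 2 for control EBs, n = 3 for iHCs). Cyp26b1 stands at 8.60 in Dox+RA and 6.13 in Dox iHCs at day 12.

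Whether the effect of RA differed between the days was tested as an interaction. In limma 2 genes were called, both lower at day 12, while 1276 had an unadjusted p under 0.05. Mx2 had an interaction of -1.89 ± 0.17 (adjusted p = 0.00054), from an RA effect of 2.13 at day 8 to 0.24 at day 12. Cbln2 had -1.32 ± 0.19 (adjusted p = 0.049; range over alternatives 0.00444 to 0.261). The interferon-stimulated list, chosen after the data were seen, was lower at day 12 than at day 8 in this test (adjusted p = 7.3e-32, adjusted p = 0.0023 with an estimated correlation). Over all 45 genes the median difference with RA was 0.509 at day 8 and 0.176 at day 12. Stereocilia genes were also lower as a list (median -0.28, adjusted p = 1.1e-09, adjusted p = 0.13 with an estimated correlation). So were hair cell identity genes (median -0.44, adjusted p = 5.9e-07, adjusted p = 0.13 with an estimated correlation) and synapse genes (median -0.22, adjusted p = 5.6e-05, adjusted p = 0.20 with an estimated correlation), with 0 single members called in these lists. Cell cycle genes were higher (median 0.33, adjusted p = 1.6e-05, adjusted p = 0.77 with an estimated correlation). Myo7a had an interaction of -1.02 ± 0.35 (adjusted p = 0.71).

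The mesenchyme list in this interaction (median 0.23, adjusted p = 0.0028, adjusted p = 0.77 with an estimated correlation; range 2.06e-06 to 0.769) lost its call without Dox day 12 replicate 1 (0.076) or Dox day 8 replicate 3 (0.067). The Merkel cell list (median -0.30, adjusted p = 0.014, adjusted p = 0.20 with an estimated correlation; range 0.000414 to 0.198) lost its call without Dox day 12 replicate 1 (0.063), Dox day 8 replicate 2 (0.077) or Dox+RA day 8 replicate 3 (0.061). Cbln2 lost its call without replicate 2 of Dox day 8, Dox+RA day 8, Dox day 12 or Dox+RA day 12 (adjusted p = 0.261, 0.150, 0.0968 and 0.164; range over alternatives 0.00444 to 0.261). It also did so without replicate 1 of Dox or Dox+RA at day 12 (0.0873 and 0.166) or replicate 3 of Dox or Dox+RA at day 8 (0.185 and 0.115). The count was 9 without Dox day 8 replicate 1, 6 without Dox+RA day 8 replicate 1, 5 without Dox day 12 replicate 3, 15 without Dox+RA day 12 replicate 3 and 1 without any of the other 8 iHC arrays. With replicates as a block it was 15.

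Change over time was asked first of Dox iHCs, from day 8 to day 12. Between these days Lhfpl5 and Ptprq were among the genes that rose, and Top2a and the Notch target Hey1 among those that fell. Atoh1 (0.30 ± 0.13, adjusted p = 0.19), Pou4f3 (0.07 ± 0.17, adjusted p = 0.88), Gfi1 (0.03 ± 0.10, adjusted p = 0.90) and Myo7a (0.39 ± 0.25, adjusted p = 0.41) were not called. In limma 1785 genes were called (8.05%), 751 higher and 1034 lower at day 12, and 277 differed 2-fold or more. Rap1gap stood at 7.60 ± 0.03 (SD, n = 3) at day 12 against 5.77 ± 0.08 (n = 3), a rise of 1.83 ± 0.15 (adjusted p = 5.4e-05). Lhfpl5 (1.83 ± 0.29), Tafa1 (1.70 ± 0.31), Cbln2 (1.66 ± 0.13), the meiotic helicase gene Hfm1 (1.66 ± 0.28) and the claudin gene Cldn9 (1.59 ± 0.22) also rose. Sst (-3.53 ± 0.57, adjusted p = 0.0032), the guidance receptor gene Robo1 (-2.04 ± 0.33), Arhgap28 (-2.04 ± 0.19), the neurotrophin receptor gene Ntrk3 (-2.0 ± 0.25), the helix-loop-helix gene Olig3 (-1.90 ± 0.29) and the LIM homeobox gene Isl1 (-1.87 ± 0.30) fell.

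Stereocilia genes rose in 16 of 32 cases with 0 falls and 16 not called (adjusted p = 4.4e-09, adjusted p = 0.26 with an estimated correlation; 18 and 2 adjusted over the list alone). Among them were the stereocilia membrane phosphatase gene Ptprq (1.37 ± 0.24) and the calcium pump gene Atp2b2 (1.23 ± 0.16). Synapse genes had 3 rises, 1 fall and 17 not called (adjusted p = 0.0010, adjusted p = 0.31 with an estimated correlation; 10 and 3 adjusted over the list alone). The calcium channel gene Cacna1d changed by 1.18 ± 0.22. Cell cycle genes fell in 20 of 29 cases, with 9 not called (adjusted p = 4.1e-19, adjusted p = 0.26 with an estimated correlation; 24 falls adjusted over the list alone). They included Top2a (-1.37 ± 0.18), Cdk1 (-1.37 ± 0.22) and Ccnb2 (-1.19 ± 0.18). Notch genes had 0 rises, 6 falls and 14 not called (adjusted p = 0.00019, adjusted p = 0.26 with an estimated correlation; 1 and 8 adjusted over the list alone), with Hey1 at -1.39 ± 0.21. Blood genes had 0, 4 and 20 (adjusted p = 0.00024, adjusted p = 0.33 with an estimated correlation; 7 falls adjusted over the list alone). Hbb-bh1 changed by -0.76 ± 0.16. Fbxo2 (1.12 ± 0.21) and Krt20 (1.15 ± 0.23) rose, and Prph (-1.08 ± 0.17), Myc (-1.60 ± 0.25) and Cdkn1c (-1.33 ± 0.23) fell. Hair cell identity genes (4, 1 and 20; adjusted p = 0.0080, adjusted p = 0.35 with an estimated correlation; range 0.000457 to 0.352) lost their call without Dox day 12 replicate 1 (0.053). Merkel cell genes (4, 1 and 7; adjusted p = 0.035, adjusted p = 0.26 with an estimated correlation; range 0.0058 to 0.260) lost theirs without Dox day 12 replicate 1 (0.091) or Dox day 8 replicate 2 (0.066), and with quantile scaling (0.0578) or cyclic loess (0.0508). The count was 644 without Dox day 12 replicate 1, 705 without Dox day 8 replicate 2, 982 without Dox day 12 replicate 2 and 784 without Dox day 8 replicate 3. With replicates as a block it was 3139, and with the compared arrays alone 420.

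In Dox+RA iHCs 22 of the 24 interferon-stimulated genes called higher with RA at day 8 fell by day 12, as did the neurofilament gene Nefl, and the channel genes Cacna1i and Kcng1 rose. The day 8 Dox+RA arrays that chose these 24 genes are also the baseline here, which favours a fall. In limma 972 genes were called (4.38%), 394 higher and 578 lower, and 183 differed 2-fold or more. Usp18 stood at 6.95 ± 0.31 (SD, n = 3) at day 12 against 9.27 ± 0.27 (n = 3), a fall of -2.32 ± 0.26 (adjusted p = 0.00048), and Oas1b (-2.07 ± 0.24), Parp12 (-1.94 ± 0.26) and Oasl2 (-1.92 ± 0.25) fell as well. Of the 45 interferon-stimulated genes 22 fell (adjusted p = 2.9e-23, adjusted p = 0.0076 with an estimated correlation). The other large falls were Sst (-3.89 ± 0.57), Nefl (-2.62 ± 0.31), the acetylcholine receptor subunit Chrng (-2.39 ± 0.27), Isl1 (-2.32 ± 0.30), Alox5ap (-2.32 ± 0.41) and the secretion gene Cadps2 (-2.16 ± 0.20). Rises were led by the T-type calcium channel gene Cacna1i (1.68 ± 0.21, adjusted p = 0.00082), Grip2 (1.68 ± 0.23), the pentraxin gene Nptx1 (1.64 ± 0.23), the potassium channel gene Kcng1 (1.59 ± 0.23), Col12a1 (1.56 ± 0.20) and Foxd2 (1.55 ± 0.27). Whrn, of the stereocilia tip, rose by 0.79 ± 0.12, and Sox2 (-0.98 ± 0.15), Pou4f1 (-0.75 ± 0.11), Meis2 (-1.12 ± 0.13) and Cdkn1c (-1.57 ± 0.23) fell. Atoh1 (-0.04 ± 0.13, adjusted p = 0.93) and Myo7a (-0.63 ± 0.25, adjusted p = 0.18) were not called.

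Cell cycle genes fell in 5 of 29 cases in Dox+RA iHCs over time (adjusted p = 2.5e-11, adjusted p = 0.57 with an estimated correlation; 13 falls adjusted over the list alone). Blood genes fell in 2 of 24 (adjusted p = 0.00012, adjusted p = 0.57 with an estimated correlation; 3 falls adjusted over the list alone). Stereocilia genes had 1 rise, 2 falls and 29 not called (adjusted p = 0.37). Notch genes (0, 0 and 20; adjusted p = 0.0066, adjusted p = 0.57 with an estimated correlation; range 0.000224 to 0.573) lost their call without Dox+RA day 8 replicate 3 (0.097). Neuronal genes (1, 5 and 29; adjusted p = 0.018, adjusted p = 0.74 with an estimated correlation; range 0.00144 to 0.744) lost theirs without Dox+RA day 12 replicate 1 (0.083) or replicate 2 (0.063) or Dox+RA day 8 replicate 3 (0.18). The call of cyclin-dependent kinase inhibitors (0, 1 and 6; adjusted p = 0.032, adjusted p = 0.57 with an estimated correlation; range 0.00335 to 0.573) was lost without Dox+RA day 8 replicate 1 (0.24) or Dox+RA day 12 replicate 2 (0.074) or replicate 3 (0.077), and with quantile scaling (0.0706) or cyclic loess (0.0511). The count was 419 without Dox+RA day 12 replicate 1, 364 without Dox+RA day 8 replicate 2, 297 without Dox+RA day 12 replicate 2 and 574 without Dox+RA day 8 replicate 3. With replicates as a block it was 2010.

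Control EBs were followed from day 8 to day 12 to show what changes without the switch. The collagen gene Col6a1 and Alb, which codes for albumin, were among the genes that rose, and the globin gene Hbb-y and the cardiac Myh7 among those that fell. Rxfp2, a receptor of the relaxin family, rose from 3.17 ± 0.26 (SD, n = 2) to 7.55 ± 0.44 (n = 2), a difference of 4.38 ± 0.26 (adjusted p = 2.8e-07). Alb (4.19 ± 0.18), the collagen cross-linking enzyme gene Lox (3.25 ± 0.28), Angptl7 (2.92 ± 0.19) and Slitrk6 (2.59 ± 0.21) rose too. The red cell anion exchanger gene Slc4a1 (-3.32 ± 0.44, adjusted p = 0.00036), the blood group gene Kel (-2.89 ± 0.33), Hsd3b6 (-2.74 ± 0.34), Grap2 (-2.71 ± 0.22) and Pkhd1l1 (-2.67 ± 0.22) fell. In limma 831 genes were called (3.75%), 516 higher and 315 lower, and 307 differed 2-fold or more. Atoh1 (0.13 ± 0.16, adjusted p = 0.81), Pou4f3 (-0.50 ± 0.21, adjusted p = 0.28) and Gfi1 (-0.01 ± 0.13, adjusted p = 0.99) were not called.

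Mesenchyme genes rose in 6 of 25 cases in control EBs, with 19 not called (adjusted p = 8.2e-07, adjusted p = 0.30 with an estimated correlation; 10 rises adjusted over the list alone). Among them were the collagen genes Col6a1 (2.52 ± 0.16), Col6a2 (2.43 ± 0.16) and Col1a2 (1.44 ± 0.18) and the mesenchymal factor Tcf21 (1.43 ± 0.12). Blood genes had 1 rise, 10 falls and 13 not called (adjusted p = 8.2e-07, adjusted p = 0.30 with an estimated correlation; 3 and 11 adjusted over the list alone). Hbb-y changed by -2.62 ± 0.22, Hbb-bh1 by -2.43 ± 0.19 and Hba-x by -1.61 ± 0.25. Mesoderm and cardiac genes had 0, 5 and 20 (adjusted p = 4.9e-05, adjusted p = 0.30 with an estimated correlation; 1 and 11 adjusted over the list alone), with the myosin gene Myh7 at -1.55 ± 0.18. Retinoic acid response genes had 4, 1 and 17 (adjusted p = 0.012, adjusted p = 0.30 with an estimated correlation; 6 and 1 adjusted over the list alone). Neuronal genes (4, 0 and 31; adjusted p = 0.034, adjusted p = 0.73 with an estimated correlation; range 0.0132 to 0.730) lost their call without replicate 1 of day 8 (0.15) or of day 12 (0.11) or with quantile scaling (0.0995). Endoderm genes (5, 0 and 21; adjusted p = 0.0014, adjusted p = 0.73 with an estimated correlation; range 1.45e-08 to 0.730) lost it without day 12 replicate 2 (0.21). Cell cycle genes (0, 0 and 29; adjusted p = 0.014, adjusted p = 0.79 with an estimated correlation; range 0.000154 to 0.914) lost it without replicate 2 of day 8 (0.91) or of day 12 (0.077) or with quantile scaling (0.118). The pluripotency list (0, 3 and 21; adjusted p = 0.012, adjusted p = 0.73 with an estimated correlation; range 2.85e-06 to 0.914) pointed the other way without day 8 replicate 2 (0.91). The count was 384 without day 12 replicate 1 and 317 without day 8 replicate 2, and 553 with the compared arrays alone.

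The last pair of tests asked whether iHCs changed over time differently from control EBs. For Dox iHCs 630 genes were called in the interaction, 229 with a higher and 401 with a lower change than in control EBs, 383 of them 2-fold or more. Rxfp2 (-4.65 ± 0.34, adjusted p = 6.4e-06), Alb (-4.07 ± 0.23), Nefl (-3.27 ± 0.48) and Lox (-3.27 ± 0.36) had lower changes than in control EBs. So had Ntrk3 (-2.86 ± 0.39), Col6a1 (-2.64 ± 0.21), Col6a2 (-2.48 ± 0.21), Col4a1 (-1.44 ± 0.25), Col1a2 (-1.34 ± 0.24) and Meis2 (-1.30 ± 0.20). Higher changes were those of Grap2 (2.97 ± 0.29, adjusted p = 6.4e-05), Cited4 (2.90 ± 0.37), Hbb-y (2.62 ± 0.28), Slc18a2 (2.18 ± 0.16), Hbb-bh1 (1.66 ± 0.25), Cbln2 (1.59 ± 0.21) and Myh7 (1.5 ± 0.23). Rxfp2 stood at 3.20 ± 0.04 (SD, n = 3) in Dox iHCs of day 12 against 3.47 ± 0.27 at day 8, beside its rise of 4.38 in control EBs, and Hbb-y was 4.69 at both days, beside a fall of -2.62 in control EBs. Stereocilia genes as a list were higher (2 rises, 0 falls and 30 not called; adjusted p = 2.1e-06, adjusted p = 0.25 with an estimated correlation), as were synapse genes (2, 0 and 19; adjusted p = 0.00014, adjusted p = 0.25 with an estimated correlation). Mesenchyme genes (0, 5 and 20; adjusted p = 6.2e-09, adjusted p = 0.25 with an estimated correlation) and endoderm genes (0, 5 and 21; adjusted p = 8.3e-05, adjusted p = 0.43 with an estimated correlation) were lower. The same held for retinoic acid response genes (0, 3 and 19; adjusted p = 0.00089, adjusted p = 0.25 with an estimated correlation) and cell cycle genes (0, 1 and 28; adjusted p = 9.2e-08, adjusted p = 0.43 with an estimated correlation). The count was 291 without control EB day 12 replicate 1, 266 without control EB day 8 replicate 2, 414 without Dox day 8 replicate 2, 396 without control EB day 12 replicate 2 and 1068 without Dox day 12 replicate 3. With the compared arrays alone it was 415.

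For Dox+RA iHCs 582 genes were called in the interaction with control EBs over time, 212 higher and 370 lower, 347 of them 2-fold or more. Rxfp2 (-4.95 ± 0.34, adjusted p = 3.1e-06), Sst (-4.61 ± 0.91), Nefl (-4.18 ± 0.48), Alb (-4.14 ± 0.23) and Slitrk6 (-3.59 ± 0.27) had the largest negative values. Cited4 (3.38 ± 0.37, adjusted p = 0.00020), Myl7 (3.01 ± 0.60), Grap2 (2.59 ± 0.29), the ammonium channel gene Rhag (2.35 ± 0.35) and Hbb-y (2.21 ± 0.28) had the largest positive ones. Neuronal genes (0 higher, 4 lower and 31 not called; adjusted p = 0.00033, adjusted p = 0.52 with an estimated correlation) and mesenchyme genes (0, 4 and 21; adjusted p = 0.00015, adjusted p = 0.52 with an estimated correlation) were lower as lists. So were endoderm genes (0, 2 and 24; adjusted p = 0.00019, adjusted p = 0.66 with an estimated correlation) and retinoic acid response genes (0, 2 and 20; adjusted p = 0.013, adjusted p = 0.52 with an estimated correlation). Interferon-stimulated genes had 17 members called lower (adjusted p = 1.3e-16, adjusted p = 0.024 with an estimated correlation). Sst (range over alternatives 0.00056 to 0.0722) and Myl7 (range 0.00286 to 0.0972) lost their call without control EB day 12 replicate 1 (adjusted p = 0.0722 and 0.0678) or control EB day 8 replicate 2 (0.0720 and 0.0972). The count was 272 without control EB day 12 replicate 1, 268 without control EB day 8 replicate 2 and 378 without Dox+RA day 12 replicate 2.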

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

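The tests of the next 3 patterns were chosen only after the results had been seen, while the splits of arrays that follow them were planned before the data were examined.

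Genes abundant in control EBs were lower in Dox+RA than in Dox iHCs at day 8. A share of whole-EB cells in the Dox sort stays open. Of 108 genes at log2 8 or more in day 8 control EBs and at least 3 lower in Dox+RA iHCs of that day, 37 were called lower with RA. Of the 108, 63 (58.3%) implied a share more than 2 times from the median of 5.24% (1.91%, 5.95% and 9.35% in replicates 1, 2 and 3), and 14 of them (13 percent of the 108; 95% interval 7.3 to 20.8) did so beyond the 95% range of the fit's SE. The low Dox+RA value that makes the pattern also chose these genes, so this does not decide. With the difference of 3 taken at day 12 instead, 154 genes were chosen, 98 of them also among the 108, and 55 of the 154 were called lower (median of all 154 -0.732). Under 3 other scalings at least 51 of the 154 were called lower, with medians from -0.719 to -0.702 (SE up to 0.057, with genes taken as independent). These scalings start from RMA values already set to a common distribution, so they cannot decide whether scaling of the arrays plays a part. Of these 154, 80 (51.9%) lay more than 2 times from the median of 7.61%, and 29 (18.8%; 95% interval 13 to 25.9) did so beyond the 95% range of the fit's SE, an interval that holds the limit of 25% set for such genes. For the 9 cell cycle genes among the 108 the median implied share was 14.92% against 4.71% for the other 99 and an upper limit of 9.67% in random sets of such genes. Among the 154 it was 15.06% for 13 cell cycle genes, 9 of them the same, against a limit of 13.16%. Random sets leave out that members move together (estimated correlation 0.669), so the shares were also taken in each same-numbered pair of arrays: the cell cycle median was 2.22, 2.35 and 2.28 times that of the other genes (95% interval of the mean by t 2.13 to 2.44). All 3 ratios use the same mean of the day 8 control EBs and the same genes. The interval therefore leaves out error in the EB levels and in the choice of genes. Within that limit, for the 13 cell cycle genes among the 154, these ratios argue against a share of cells like the untreated control EBs as their only source. Unsorted EBs treated with Dox were not measured, so a share of cells from those stays open. An effect of RA on these genes remains open and was not tested.

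Of 32 stereocilia and mechanotransduction genes 12 were called higher in Dox+RA than in Dox iHCs at day 8 and 20 were not called (adjusted p = 1.5e-12, adjusted p = 0.12 with an estimated correlation). Fewer converted cells in the Dox sort would lower a gene more, the further it stands above control EBs. Among 511 genes at least 2 (log2) above control EBs in day 8 Dox+RA iHCs, the list had 12 members with a median log2 difference of 1.106, which is 0.667 above the median of 0.439 (95% range 0.167 to 0.741) in 10000 level-matched random lists. With the difference of 2 taken in Dox+RA iHCs of day 12 instead, 11 members among 545 genes had a median of 1.109 against 0.458 (0.200 to 0.802). Array by array, which allows for members that move together, these members were 0.663 higher with RA than the other genes of the 545 (95% interval by t 0.1 to 1.226, 3 arrays in each group). This argues against the explanation for these members. They hold 8 of the 12 members called higher with RA, and the median over all 32 members was 0.424, so for the others it stays open. An effect of RA on these genes stays open and was not tested, as does a difference in how the replicates of each treatment were sorted.

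Interferon-stimulated genes were higher in Dox+RA than in Dox iHCs at day 8. The 24 called genes had a median of 1.045 (SE 0.121, with genes taken as independent) above control EBs of the same day. The same day 8 Dox+RA values chose these genes, which raises this median. Of the 24, 21 were called higher than in control EBs. For these 21 a share of cells like the untreated control EBs in the Dox+RA sort is argued against, since such cells cannot bring a gene above the EB level. Unsorted EBs treated with Dox and RA were not measured, so a share of cells from those stays open. Over all 45 genes of the list the median was 0.48, with 23 called higher and 4 lower (adjusted p = 0.22 with an estimated correlation). An effect of RA on these genes, or of the culture or handling of these arrays, stays open, because neither was tested and the batches are not given in the sources used here.

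Only 10 splits of 6 arrays into 3 and 3 exist, too few for a share under 0.05. For Dox+RA against Dox at day 8 the real grouping called 1094 genes and the highest other split 0, so 1 split of 10 called as many. The values were 205 and 2 at day 12, 1785 and 115 for Dox iHCs over time and 972 and 1 for Dox+RA iHCs over time, again 1 split of 10 in each. For the interaction of RA and day 13 of 100 drawn splits called 2 genes or more, with 3402 in the highest. These splits exchange arrays of different days and so carry the day differences, and chance cannot be excluded for this count.

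The effect of RA differed between the days in 2 genes, Mx2 (-1.89) and Cbln2 (-1.32), the latter without a call in 12 of 23 settings. Change over time differed from that of control EBs in 630 genes for Dox iHCs and 582 for Dox+RA iHCs. For Dox iHCs the largest differences were 2.97 for Grap2, 2.90 for Cited4, 2.62 for Hbb-y, 2.45 for Myl7, 2.40 for Hsd3b6, -4.65 for Rxfp2, -4.24 for Sst, -4.07 for Alb, -3.27 for Nefl and -3.27 for Lox. Of these Hsd3b6 (adjusted p = 0.0584; range over alternatives 0.000902 to 0.0584), Sst (0.102; range 0.00091 to 0.102) and Myl7 (0.149; range 0.00516 to 0.219) lost their call without control EB day 12 replicate 1. Without control EB day 8 replicate 2 the adjusted p was 0.101 for Sst and 0.219 for Myl7, and without control EB day 12 replicate 2 it was 0.0524 and 0.110. Without Dox day 12 replicate 2 it was 0.0504 and 0.0952, and for Myl7 it was also 0.0693 without Dox day 8 replicate 1 and 0.0772 without Dox day 8 replicate 2. For Dox+RA iHCs the largest differences were 3.38 for Cited4, 3.01 for Myl7, 2.59 for Grap2, 2.35 for Rhag, 2.21 for Hbb-y, -4.95 for Rxfp2, -4.61 for Sst, -4.18 for Nefl, -4.14 for Alb and -3.59 for Slitrk6. Among the 10187 table entries without a single gene symbol, 201 and 292 were called 2-fold or more above control EBs in Dox iHCs at day 8 and day 12, and 266 and 330 in Dox+RA iHCs.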

How the results depend on the processing

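Leaving out the Dox iHCs of replicate 3, leaving out single arrays for the lists, the lists under 3 scalings, the genes picked by day 12 values for the implied share and the stereocilia test, and scalings for EB-abundant genes alone were chosen only after the results had been seen, and the other alternatives were planned. Counts of genes against control EBs and their overlap between days stayed within 1.5 times under all of them. No named gene that was called in a comparison turned its direction there, while differences near 0 without a call could change sign. Calls were less stable than directions. For Dox+RA against Dox, 36 of 64 called named genes kept their call under every alternative at day 8 and 11 of 28 at day 12. Over time 25 of 58 did in Dox iHCs, 21 of 50 in Dox+RA iHCs and 21 of 44 in control EBs. Against control EBs 90 of 94 did for Dox iHCs at either day, and 90 of 93 and 93 of 95 for Dox+RA iHCs at day 8 and day 12. For Dox+RA against Dox at day 8 (1094 genes) array weights gave 2277, the replicate block 2436, and both Dox replicate 3 arrays left out 687. Leaving out single arrays gave 333 (Dox day 8 replicate 2) to 1559 (Dox day 8 replicate 1), with 625 and 546 without Dox+RA day 8 replicates 1 and 2 and 416 without Dox day 8 replicate 3. At day 12 (205) the compared arrays alone gave 29, weights 635 and the block 722. Single arrays left out gave 55 (replicate 2 of either group) to 393 (Dox replicate 1), with 80 and 360 without Dox+RA replicates 1 and 3. For Dox iHCs over time (1785) the values were 420, 3023 and 3139. Without 1 array they ran from 644 (without Dox day 12 replicate 1) to 2598 (without Dox day 12 replicate 3), with 705 and 784 without Dox day 8 replicates 2 and 3 and 982 without Dox day 12 replicate 2. For Dox+RA iHCs over time (972) weights gave 2299 and the block 2010. Single arrays left out gave 297 (without Dox+RA day 12 replicate 2) to 998 (without Dox+RA day 12 replicate 3), with 419 without Dox+RA day 12 replicate 1 and 364 and 574 without Dox+RA day 8 replicates 2 and 3. For control EBs over time (831) the compared arrays alone gave 553 and the block 1255. Single arrays left out gave 317 (without day 8 replicate 2) to 951 (without day 8 replicate 1), with 384 without day 12 replicate 1. For the interaction of RA and day (2) the compared arrays alone, the variance trend and all entries of the table gave 1 each, weights 24 and the block 15. Single arrays left out gave 1 to 15, the latter without Dox+RA day 12 replicate 3, with 9 and 6 without replicate 1 of Dox and Dox+RA at day 8, 5 without Dox day 12 replicate 3 and 1 without any of the other 8. For the interaction of Dox iHCs and time (630) the values were 415 with the compared arrays, 1021 with weights, and 1430 with the block. Without 1 array they ran from 266 (without control EB day 8 replicate 2) to 1068 (without Dox day 12 replicate 3), with 291 and 396 without control EB day 12 replicates 1 and 2 and 414 without Dox day 8 replicate 2. For that of Dox+RA iHCs (582) they were 942 with weights, and 1150 with the block. Without 1 array they ran from 268 (without control EB day 8 replicate 2) to 686 (without Dox+RA day 12 replicate 3), with 272 without control EB day 12 replicate 1 and 378 without Dox+RA day 12 replicate 2. Fewer arrays give less precision, and otherwise the cause of these shifts was not tested. With an estimated correlation the lists called went from 14 to 8 for Dox against control EBs at day 8, and from 14 to 7 at day 12. They went from 13 to 0 for Dox+RA against control EBs at day 12, from 11 to 0 for Dox+RA against Dox at day 8 and from 5 to 2 at day 12. They went to 0 from 7 for Dox iHCs over time, from 5 for Dox+RA iHCs over time, from 8 for control EBs over time, from 6 for the interaction of RA and day, and from 11 and 9 for the interactions of Dox and of Dox+RA with time. With 1 array left out, 4 to 8 lists were called for Dox+RA against Dox at day 12, 5 to 12 for Dox iHCs over time, 3 to 5 for Dox+RA iHCs over time and 4 to 10 for the interaction of RA and day. No called list turned its direction under a scaling, but without control EB day 8 replicate 2 the pluripotency list turned in control EBs over time (adjusted p = 0.914; range over alternatives 2.85e-06 to 0.914) and in the interaction of Dox+RA and time (adjusted p = 0.928, against 3.77e-05 without control EB day 8 replicate 1, which are the ends of its range). Lists that lost their call under a scaling were Notch at day 8 with RA (0.0865 with quantile scaling, 0.101 with cyclic loess), Merkel cell in Dox iHCs over time (0.0578, 0.0508) and kinase inhibitors in Dox+RA iHCs over time (0.0706, 0.0511). Further ones were neuronal (0.0995) and cell cycle (0.118) in control EBs over time with quantile scaling and, in the interaction of Dox and time, blood and endothelium (0.0642 with quantile scaling, 0.0880 with equal medians), hair cell identity and mesoderm (0.0510 each with equal medians). With dim genes left out the lists without their call were Hox paralogues 1 to 5 in Dox iHCs against control EBs at day 12 (0.0743), Notch (0.141), mesoderm (0.166) and endoderm (0.0799) at day 8 with RA, and pluripotency (0.0868) and kinase inhibitors (0.0953) in the interaction of Dox+RA and time. The block and the variance trend ended no list's call. The stereocilia list gained a call in Dox+RA against Dox at day 12 (0.0361 with quantile scaling, 0.0205 with cyclic loess, 0.0449 with equal medians, 0.0193 with the block, 0.0136 with dim genes left out; range 0.00181 to 0.780). So did surface epithelium (0.00150 with the block, 0.0402 with dim genes left out, 0.0478 with cyclic loess, 0.0425 with equal medians), which also gained one at day 8 with the block (0.0334) and in Dox iHCs against control EBs at day 8 with the block (0.0281). Equal medians gave a call to retinoic acid response and mesenchyme in Dox iHCs over time (0.0434 each) and to Notch in the interaction of Dox+RA and time (0.0468). Leaving out dim genes gave one to Hox paralogues 6 to 13 in Dox+RA iHCs (0.0416) and control EBs over time (0.0210) and in the interaction of RA and day (0.0309).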

Other observations

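The lists in this part, and the genes named from them, were chosen only after their values had been seen. Imprinted genes, which are read from 1 parental copy, were lower in iHCs than in control EBs: of 32 measured, 21 fell and 3 rose in Dox iHCs at day 8 (camera adjusted p = 7.1e-06, adjusted p = 0.071 with an estimated correlation) and 20 fell and 1 rose at day 12 (adjusted p = 2.2e-07). In Dox+RA iHCs 20 fell and 3 rose at day 8 (adjusted p = 1.2e-07) and 21 fell and 0 rose at day 12 (adjusted p = 7.4e-09). At day 8 Asb4 (-4.31), Plagl1 (-3.14), Phlda2, a gene that restrains placental growth (-2.95), and the Notch-related Dlk1 (-2.72) fell in Dox iHCs. With RA 7 imprinted genes were lower than with Dox alone at day 8 (adjusted p = 1.7e-06), where Zim1 changed by -1.80, the adaptor gene Grb10 by -1.60 and Peg3 by -0.88. The 43 entries named for microRNA genes between Dlk1 and Dio3, an imprinted region, fell in 40 cases in Dox iHCs at day 8 (median -1.29, adjusted p = 2.5e-17, adjusted p = 0.12 with an estimated correlation) and in 39 at day 12 (-1.34, adjusted p = 8.2e-14, adjusted p = 0.19 with an estimated correlation). In Dox+RA iHCs 40 fell at day 8 (-1.50, adjusted p = 3.0e-16, adjusted p = 0.11 with an estimated correlation) and 39 at day 12 (-1.53, adjusted p = 1.6e-15, adjusted p = 0.15 with an estimated correlation).

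Ribosomal protein genes fell as well: of 63, 18 fell and 0 rose in Dox iHCs at day 8 (adjusted p = 0.0042, adjusted p = 0.41 with an estimated correlation). At day 12, 36 fell and 2 rose (adjusted p = 1.1e-06, adjusted p = 0.19 with an estimated correlation). Rps12 changed by -1.65, Rpl32 by -1.25 and Rps24 by -1.18. In Dox iHCs over time 28 fell (adjusted p = 1.2e-21, adjusted p = 0.051 with an estimated correlation), and 13 were lower with RA at day 8 (adjusted p = 3.1e-16). Ion channel subunit genes rose in 39 and fell in 14 of 126 cases in Dox iHCs at day 8 (adjusted p = 0.00036, adjusted p = 0.12 with an estimated correlation). They included the potassium channel genes Kcnk9 (3.85), Kcnd2 (3.52) and Kcnh3 (2.88) and the calcium channel genes Cacna2d2 (3.69) and Cacna1b (2.47), which rose. In Dox+RA iHCs at day 12 the counts were 52 and 21 (adjusted p = 0.0024, adjusted p = 0.16 with an estimated correlation). In control EBs over time 11 of 44 collagen genes rose and 0 fell (adjusted p = 1.3e-11, adjusted p = 0.064 with an estimated correlation), led by Col6a1 (2.52), Col6a2 (2.43) and Col12a1 (2.23). Of 35 protocadherin genes 13 rose and 0 fell (adjusted p = 3.5e-14, adjusted p = 0.064 with an estimated correlation). They included Pcdhb13 (1.62), Pcdhb14 (1.58) and Pcdhb11 (1.45).

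Of the 45 interferon-stimulated genes 18 were lower and 1 was higher in Dox iHCs than in control EBs at day 8 (adjusted p = 0.0042, adjusted p = 0.37 with an estimated correlation). In Dox+RA iHCs of that day 23 were higher and 4 lower than in control EBs (adjusted p = 0.00089, adjusted p = 0.22 with an estimated correlation). At day 12 only Lgals3bp of the 45 was called higher with RA than without (0.63, adjusted p = 0.030). As a list the 45 genes were still higher with RA at that day. Their median was 0.176 (camera adjusted p = 1.3e-05, adjusted p = 0.18 with an estimated correlation).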
